A study of Mus musculus with 84 samples.

How the data were processed

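The data are read counts of 84 bulk RNA sequencing libraries from sorted mouse microglia, in 22 groups of treatment, day and library year. Per the labels' protocols, RNA of sorted cells was isolated with the PicoPure kit, cDNA was amplified by 11 cycles of PCR, and libraries were made with the Nextera XT kit. Molecular identifiers are not named in the labels, so reads copied by PCR cannot be told from separate molecules. The gates of the sort are not given in the sources used here. Reads were aligned to mm10 (GRCm38) with STAR, per the submitters' processing notes, which state no version. Counts per Ensembl gene were made with HTSeq, per the file headers of the deposited run summary and the summary lines of each count file. The settings of both tools, and whether strand was used, are not given in the sources used here. Reads of a gene and of its antisense or overlapping partner, and of near-identical copies, may therefore be shared.

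The authors deposited 1 file of raw counts per library, not normalised, with 5 summary lines that name no gene. Those lines were left out of library sizes and tests. Reads in no annotated feature made up a median of 5.07% (2.593% to 22.44%) of the reads counted to genes, to no feature or as ambiguous, and reads that fit more than 1 gene made up 2.62% to 4.069%. The authors also deposited a run summary with percent values per library, such as the percent of uniquely aligned reads and of duplicates (47.03% to 75.57%); how duplicates were marked is not given in the sources used here. Of its 85 lines, 1 matched no library and was not used. The labels number 2 uninjured libraries of day 30 in different ways in their title and library name, and the number of the library name was used.

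Gene symbols, types and coordinates came from the GENCODE M21 annotation of GRCm38, which gave a symbol to 49326 of the gene identifiers. Total gene counts per library gave the depth. Libraries of a group were compared by a chi-square test of their counts over genes with at least 10 counts. The lowest chi-square per degree of freedom of any pair was 6.149, so no library was taken for a copy of another.

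Each of 14 comparisons was made within a day with edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr (minimum count 10, minimum total 15), and the quasi-likelihood F test in 1 fit of all 4 treatments of the day. Day 1 had the library year as a covariate. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called, or said to rise or fall, at an adjusted p under 0.05. All adjusted p-values of single genes are from this test unless another tool is named. Standard errors were obtained as the fold change divided by the square root of F. At day 14 vehicle was not compared with injury only, because library year and treatment cannot be told apart there. In 2 further tests over all days, an interaction of effect and day was tested for the injury and for the clodronate effect. CPM values use TMM-scaled library sizes, and log2 CPM adds a prior count of 2.

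Before the data were examined, 31 gene lists were fixed: 17 of microglial states and pathways, 3 of RNA quality and handling, and 11 of other cell types. All 494 entries were found, no gene stands in more than 1 list, and a list was tested where at least 3 members passed the filter. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with the Benjamini-Hochberg method over all lists of a comparison. Camera with a correlation estimated from the data and fry, which tests a list without regard to other genes, were alternatives. The genes named in a comparison were chosen by a rule fixed before the data were examined. Up to 8 called genes per direction with the largest fold change were eligible, with a mean log2 CPM of 3 or more and every library on the right side of the other group's median. Predicted, ribosomal protein and pseudogenes were excluded, and where fewer than 8 qualified, called genes were taken by smallest p. Up to 4 called members of each list were added. Where none was called, the 3 genes with the smallest p were eligible, and Ccr2, Ly6c2, Tmem119, P2ry12, Apoe, Il1b, Ifit3 and H2-Ab1 were eligible throughout. In the tests between days, the 10 genes with the smallest p were eligible. The values of 1 eligible gene are not reported here.

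The alternatives fixed before the data were examined were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, a fit of the compared groups alone, a block on the library number, single library years, single days left out, and each library left out in turn. Alternatives chosen after the data were seen left out libraries that stood apart or thinned day 60 counts to the shallowest library. Shared library numbers were taken to pair libraries only where every pair's deviations from the group means correlated above 0.1. This held for vehicle against injury only at day 30 (4 pairs, 0.118 to 0.251); the labels do not say what the numbers mark.

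The tests were run first on simulated counts with 200 changed genes, drawn from the means and library sizes of the real libraries. Of genes changed 2-fold and 4-fold, edgeR recovered 47% and 80% in the simulation of injury at day 1, 52% and 85% at day 7, 7% and 52% at day 14, 54% and 78% at day 30 and 20% and 57% at day 60. For clodronate against vehicle it recovered 55% and 83%, 47% and 81%, 19% and 62%, 59% and 79%, and 29% and 64% on the same days. For vehicle against injury only it recovered 55% and 82% at day 1, 47% and 73% at day 7, 58% and 84% at day 30 and 29% and 57% at day 60. It called 2 to 11 unchanged genes per simulation. Small changes at days 14 and 60 were thus often not detectable with these libraries.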

Results

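Bulk RNA sequencing was performed on microglia, the resident macrophages of the brain, sorted by flow cytometry from mice after severe traumatic brain injury. Per the study's design text, the question was how gene expression in microglia changes when peripheral monocytes are depleted with liposomes that carry clodronate, a bisphosphonate that kills phagocytes that take it up. Each of 5 days (1, 7, 14, 30 and 60 after injury) held 4 treatments: injury with clodronate liposomes, injury with vehicle liposomes, injury only, and no injury. The 84 libraries held 2 to 5 replicates per treatment, day and library year. Clodronate and vehicle libraries of day 1 came from an earlier library year (3 and 2 libraries) and a later library year (3 and 2 libraries), and all other groups from 1 library year each. The vehicle and injury-only libraries of day 14 came from different years and were not compared.

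Total gene counts per library ranged from 11145687 to 16035926 at day 1, from 1134078 to 15375096 at day 7, from 8681681 to 18654785 at day 14, from 9936026 to 16480776 at day 30 and from 1109856 to 12306417 at day 60. Injury-only libraries of day 60 held 8431455 to 12306417 counts, whereas uninjured libraries of that day held 2930843 to 3739798. One library stood apart at day 7: vehicle library 4 held 1134078 counts with 54.62% of reads uniquely aligned. The labels do not say that the libraries came from separate mice, so the p-values measure the spread between these libraries. Levels are given as CPM (counts scaled by library size), mean ± SD over libraries, and fold changes on the log2 scale with the standard error (SE) of the fit. Where a gene is said to be higher or lower in a number of libraries, those libraries lay on that side of the other group's mean. The ranges of the groups may still overlap, as for Apoe at day 1. The vehicle mean of day 1 was taken over both library years.

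**Figure D1:**
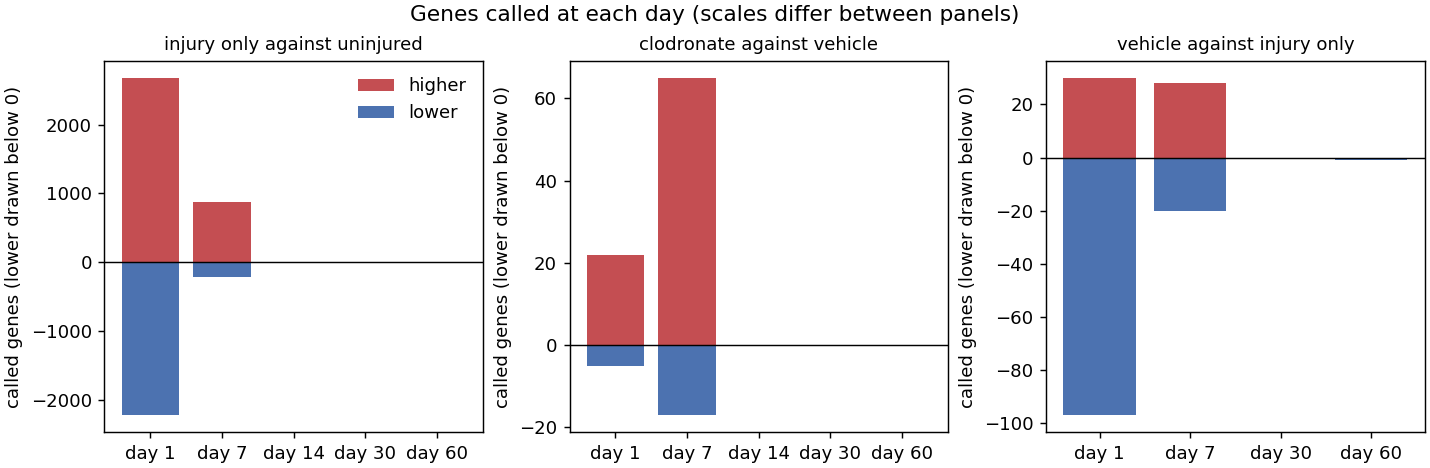
Number of genes called at adjusted p under 0.05 (vertical axis, genes; higher drawn above 0 and lower below 0) at each day for injury only against uninjured, clodronate against vehicle, and vehicle against injury only. Injury called 4906 genes at day 1 and 1097 at day 7, and clodronate called 27 and 82; the panels have different scales.

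Injury only was compared with uninjured to describe the effect of the injury. The labels call the uninjured controls sham in some places and naive in others, so it is not known whether this comparison also holds effects of surgery or anaesthesia. At day 1, all 22 measured genes of the homeostatic microglia list fell. P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), the purinergic receptor of resting microglia, fell by 2.26 on the log2 scale (SE 0.24), from 4865 ± 415 to 1013 ± 161 CPM (n = 5 and 5). Tmem119, a microglial surface protein, fell by 0.82 (SE 0.15), from 5693 ± 739 to 3225 ± 286 CPM. Adam8 (ENSMUSG00000025473, chromosome 7, 139978932 to 139992562), a membrane metalloprotease, rose from 4.72 ± 3.17 to 810.2 ± 79.4 CPM (log2 fold change 7.42, SE 0.60, adjusted p = 6.86e-09 by edgeR). The scavenger receptor Msr1 rose from 10.8 ± 2.86 to 865 ± 169 CPM, and the interleukin-1 receptor antagonist Il1rn from 3.16 ± 1.89 to 262 ± 61.5 CPM. All of these differences were present in 5 of 5 injured libraries.

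The homeostatic list had a median log2 fold change of −0.91 (camera adjusted p = 4.28e-18, adjusted p = 0.0991 with an estimated correlation), and 22 of its genes also fell when adjusted over the list alone. Siglech fell by 1.88 and Sparc by 1.31 on the log2 scale. Of 24 inflammatory cytokine and NF-kB genes, 18 rose and 2 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 3.02e-13, adjusted p = 0.115 with an estimated correlation). The chemokine Ccl12 reached 1172 ± 54.4 CPM from 199.6 ± 25.9, and Il1b, encoding interleukin-1β, reached 859 ± 309 CPM from 336 ± 76.0 (log2 fold change 1.36, SE 0.23). Of 25 disease-associated microglia genes, 13 rose and 5 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.000158, adjusted p = 0.153 with an estimated correlation). Lpl, a lipoprotein lipase, rose by 4.01 (SE 0.21) and Lgals3, or galectin-3, by 4.86 (SE 0.33), while the lipid receptor Trem2 fell by 1.27 (SE 0.14) and Apoe stood at 1361 ± 157 against 1760 ± 385 CPM (adjusted p = 0.0794 by edgeR, lower in 5 of 5 injured libraries). Of 26 interferon response genes, 14 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 3.43e-05, adjusted p = 0.261 with an estimated correlation).

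Metabolic and translation genes rose at day 1 as well. All 25 ribosomal protein genes rose, 25 also adjusted over the list alone (median 0.79, camera adjusted p = 8.56e-19, adjusted p = 0.12 with an estimated correlation). Of 16 glycolysis and hypoxia genes, 14 rose by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 1.71e-10, adjusted p = 0.12 with an estimated correlation), among them the pyruvate kinase Pkm, at 1592 ± 266 against 472 ± 60.1 CPM. Of 28 oxidative phosphorylation genes, 17 rose (19 adjusted over the list alone, camera adjusted p = 9.96e-05, adjusted p = 0.417 with an estimated correlation). Of 17 oxidative stress and iron genes, 10 rose and 1 fell by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 8.77e-08, adjusted p = 0.0853 with an estimated correlation), including sulfiredoxin (Srxn1), at 85.7 ± 13.3 against 10.6 ± 2.37 CPM. Plin2, a lipid droplet coat protein, rose by 2.90 (SE 0.22) and led the lipid efflux and storage list, in which 5 of 11 genes rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 0.0225, adjusted p = 0.115 with an estimated correlation). The alternative activation list had 5 of 7 genes up and 1 down by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.000641, adjusted p = 0.0853 with an estimated correlation), and the complement list had 5 of 12 up and 2 down in the same way (camera adjusted p = 0.0324, adjusted p = 0.12 with an estimated correlation).

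MHC class II genes and immediate early and heat shock genes fell at day 1. Of 9 MHC class II genes, 8 fell (9 adjusted over the list alone, median −1.12, camera adjusted p = 1.77e-05, adjusted p = 0.115 with an estimated correlation), with H2-Ab1 at 92.2 ± 22.9 against 346 ± 66.6 CPM. Of 22 immediate early and heat shock genes, 18 fell (20 adjusted over the list alone, median −0.98, camera adjusted p = 7.14e-15, adjusted p = 0.0853 with an estimated correlation). The HSP40 co-chaperone Dnajb1 fell by 3.32 on the log2 scale, from 3005 ± 293 to 300.5 ± 96.5 CPM, and Fos from 15640 ± 2090 to 7941 ± 1190 CPM. Genes of this list also respond to tissue handling before RNA is fixed. Of 14 MHC class I genes, 2 rose and 4 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.0808). The lysosome, cholesterol synthesis, cell cycle, endoplasmic reticulum stress, p53 response and mitochondrial genome lists were not called as sets (camera adjusted p from 0.23 to 0.8).

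Markers of blood cells differed in the same libraries. Of 13 monocyte genes 10 rose, and of 7 neutrophil genes 5 rose and 1 fell, by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0101 and 0.0214, adjusted p = 0.136 and 0.129 with an estimated correlation). The neutrophil gene S100a8 was at 1.97 ± 0.81 CPM after injury. Ccr2, the chemokine receptor of inflammatory monocytes, was at 8.88 ± 3.05 CPM after injury (log2 fold change 0.15, SE 0.28, adjusted p = 0.727 by edgeR, higher in 3 of 5 injured libraries). B cell and dendritic cell lists (2 of 5 and 3 of 7 genes fell, camera adjusted p = 0.143 and 0.299) and lists of border macrophages, neurons, astrocytes, oligodendrocyte lineage, endothelial and mural cells and erythroid cells (camera adjusted p from 0.471 to 0.957) were not called. In total 2680 genes rose and 2226 fell of 14516 tested at day 1.

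By day 7 after injury, genes of the disease-associated microglia list and interferon response genes had risen. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the main lipid carrier of the brain, rose from 2075 ± 439 to 21560 ± 3260 CPM (log2 fold change 3.38, SE 0.23, adjusted p = 1.25e-08 by edgeR, n = 5 injured and 4 uninjured). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a transmembrane glycoprotein of phagocytic cells, rose from 0.56 ± 0.53 to 163 ± 55.9 CPM, and Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), or osteopontin, from 9.52 ± 4.62 to 974 ± 205 CPM. Each difference was seen in 5 of 5 injured libraries. Of 25 disease-associated genes, 21 rose (24 adjusted over the list alone, median 1.45, camera adjusted p = 3.59e-69), and the call held with an estimated correlation (adjusted p = 6.27e-05). Of 26 interferon response genes, 24 rose (25 adjusted over the list alone, median 2.18, camera adjusted p = 4.96e-72, adjusted p = 0.000865 with an estimated correlation), including the nucleic acid sensor Zbp1, at 17.7 ± 0.36 against 1.47 ± 0.33 CPM, and Ifi27l2a, at 110.7 ± 19.9 against 9.28 ± 1.05 CPM.

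Other lists called at day 7 with an estimated correlation included MHC class I, with 7 of 14 genes up (10 adjusted over the list alone, adjusted p = 0.0217 with an estimated correlation). Its members H2-D1 and B2m, the class I light chain, rose by 1.10 (SE 0.16) and 0.96 (SE 0.19). H2 genes resemble each other, so reads may be shared among them. Glycolysis and hypoxia genes rose in 10 of 16 cases (12 adjusted over the list alone, adjusted p = 0.0217 with an estimated correlation), and lipid efflux and storage genes in 5 of 11 (6 adjusted over the list alone, adjusted p = 0.0325 with an estimated correlation). Cst7, encoding cystatin F, rose to 119 ± 15.7 from 7.19 ± 2.47 CPM, Fabp5, a fatty acid binding protein, to 39.3 ± 7.42 from 1.79 ± 0.44 CPM, and Ch25h, cholesterol 25-hydroxylase, to 40.4 ± 32.8 from 2.46 ± 0.40 CPM. Of 24 cytokine and NF-kB genes, 8 rose (9 adjusted over the list alone, camera adjusted p = 0.000145, adjusted p = 0.272 with an estimated correlation), and Il1b was at 125 ± 37.6 against 65.8 ± 37.5 CPM (adjusted p = 0.163 by edgeR, higher in 5 of 5 injured libraries). Complement C3 rose from 1.33 ± 0.42 to 25.7 ± 8.45 CPM.

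Homeostatic genes fell in 10 of 22 cases at day 7 (13 adjusted over the list alone, median −0.44, camera adjusted p = 1.16e-09, adjusted p = 0.0954 with an estimated correlation). P2ry12 stood at 3092 ± 603 against 4981 ± 478 CPM and the fructose transporter Slc2a5 at 551 ± 75.6 against 1081 ± 132 CPM. Of 22 immediate early and heat shock genes 10 fell (11 adjusted over the list alone, camera adjusted p = 1.02e-10, adjusted p = 0.135 with an estimated correlation), Hspa8 among them, at 1367 ± 193 against 2910 ± 447 CPM. Hspa1a and Hspa1b fell by 1.56 and 1.55, but these near-identical copies cannot be told apart by short reads. MHC class II genes H2-Aa and H2-Eb1 fell by 1.08 and 1.09 (3 of 9 list genes fell, 1 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.0379, adjusted p = 0.388 with an estimated correlation).

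Markers of other cells were higher beside these changes at day 7. The tight junction gene Cldn5 of endothelial cells rose from 31.8 ± 9.48 to 96.6 ± 29.3 CPM and 9 of 13 endothelial and mural genes rose, 9 also adjusted over the list alone (camera adjusted p = 6.95e-07, adjusted p = 0.135 with an estimated correlation). Gja1 and Gfap of astrocytes rose to 33.6 ± 10.9 and 12.7 ± 6.67 CPM from 4.63 ± 1.09 and 1.37 ± 0.51 CPM (3 of 8 list genes rose, 5 adjusted over the list alone, adjusted p = 0.0217 with an estimated correlation). Of 12 monocyte genes 2 rose (6 adjusted over the list alone, camera adjusted p = 0.00032, adjusted p = 0.135 with an estimated correlation), with list means of 0.75 to 1.57 log2 CPM after injury and −0.23 to 0.31 without. Of 9 neutrophil genes 1 rose (4 adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.244 with an estimated correlation). Border macrophage genes moved both ways, 1 rising and 4 falling of 12 (3 and 7 adjusted over the list alone, camera adjusted p = 0.00534, adjusted p = 0.362 with an estimated correlation), with the hyaluronan receptor Lyve1 at 1.03 ± 0.86 against 8.29 ± 3.43 CPM. In total 877 genes rose and 220 fell of 14278 tested. Leaving out 1 library lowered the count of 1097 to 692 (injury only 1), 630, 592 or 694 (uninjured 1, 2 or 3). Without injury only 2 or uninjured 4 the genes that fell were 140 and 121.

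Of the genes called on the same side at both times among 13631 tested on both days, 302 were higher (151 expected of independent lists) and 144 lower (35.6 expected). Another 35 genes were higher at day 7 and lower at day 1, and 13 were lower at day 7 and higher at day 1. Days 1 and 7 share no library.

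**Figure D2:**
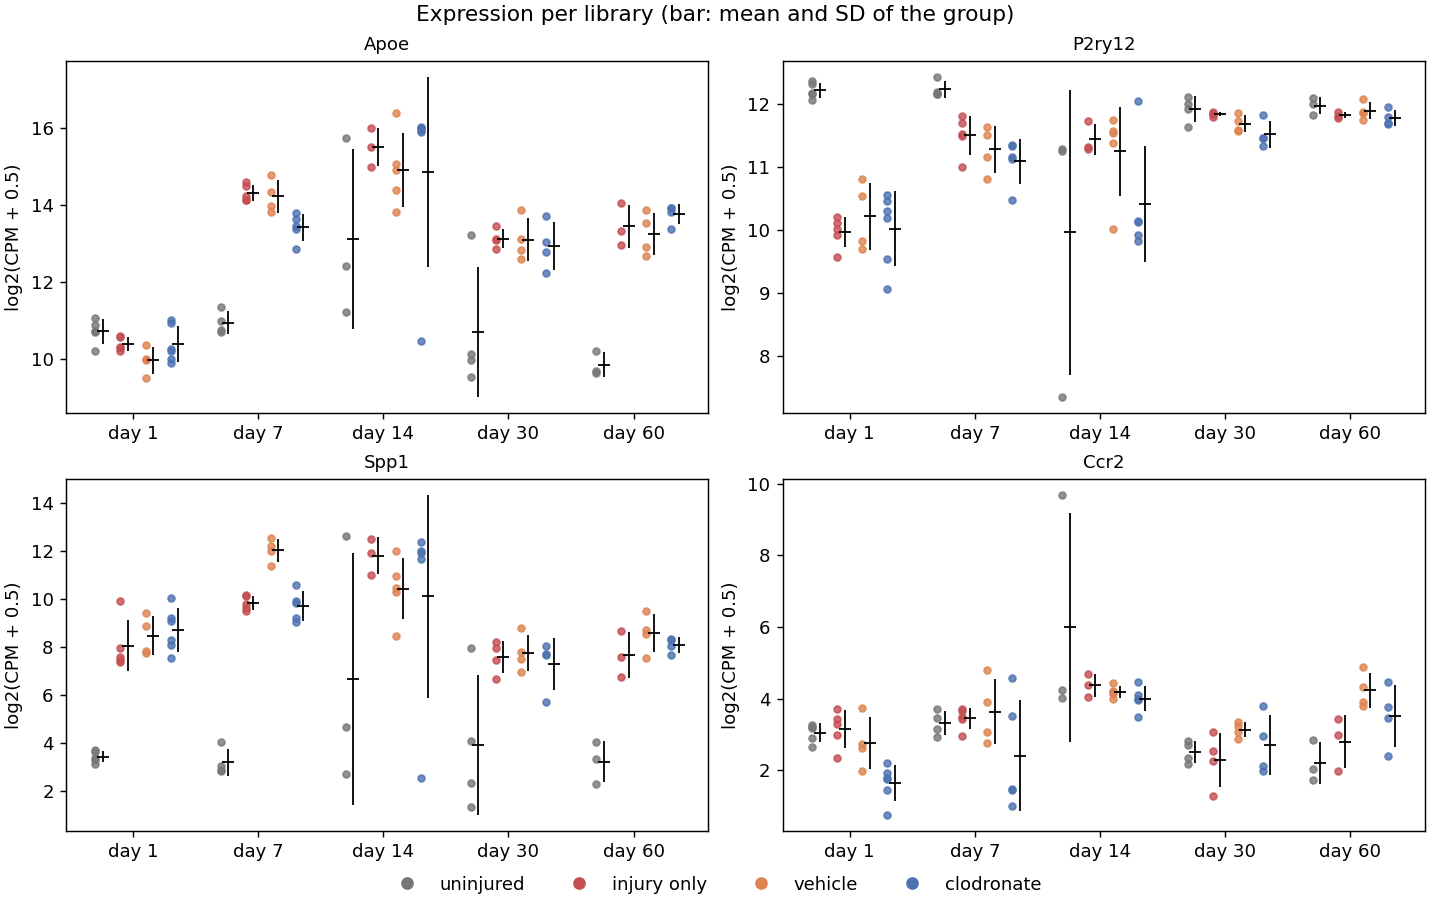
Expression of Apoe, P2ry12, Spp1 and Ccr2 in each library (vertical axis, log2 of CPM plus 0.5) by day and treatment; points are libraries and bars the group mean and SD. Apoe averaged 21560 CPM after injury against 2075 CPM in uninjured libraries of day 7, and uninjured library 3 of day 14 held 825 CPM of Ccr2.

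At day 14, no difference between injured and uninjured libraries passed the test, and the 3 uninjured libraries lay far apart. Apoe was at 46020 ± 15400 CPM after injury and 19920 ± 27900 CPM without (n = 3 and 3), and Tmem119 at 4007 ± 731 and 3263 ± 3200 CPM. Uninjured library 1 held 54230 CPM of Apoe and 6259 CPM of Spp1, uninjured library 2 held 2401 and 24.7 CPM, and uninjured library 3 held 825 CPM of Ccr2, 465 CPM of the monocyte gene Ly6c2 and 168 CPM of Tmem119. edgeR called 0 of 14354 genes, with 1963 at an unadjusted p under 0.05. DESeq2 called 97 and limma voom 0. The smallest p-values belonged to Chpf2 (57.4 ± 5.46 against 26.9 ± 10.9 CPM), Lmna (48.9 ± 7.43 against 119 ± 34.4 CPM) and Rasgrp1, each with an adjusted p of 0.316. Without uninjured library 1 the count was 1835. Monocyte genes were lower after injury (0 of 14 higher, 13 lower adjusted over the list alone, camera adjusted p = 1.72e-05, adjusted p = 0.736 with an estimated correlation). This difference lay in uninjured library 3, whose mean over the list was 8.504 log2 CPM, against 1.451 and 1.068 in uninjured libraries 1 and 2 and 1.181 to 1.801 after injury. The T and NK cell list, tested with 5 genes, had a camera adjusted p of 0.324.

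At day 30, all 25 disease-associated genes were higher after injury than without, but none was called singly. The list had a median log2 fold change of 0.45 (0 genes called adjusted over the list alone, camera adjusted p = 4.52e-20, adjusted p = 0.281 with an estimated correlation). Apoe was at 9212 ± 1590 against 3147 ± 4370 CPM (adjusted p = 1 by edgeR, higher in 4 of 4 injured libraries, n = 4 and 4) and P2ry12 at 3716 ± 74.4 against 3948 ± 528 CPM. Cell cycle genes were lower in 24 of 29 cases (median −0.53, camera adjusted p = 5.61e-07, adjusted p = 0.281 with an estimated correlation). The smallest p-values were those of Fgr, a Src-family kinase (16.3 ± 2.52 against 7.75 ± 2.92 CPM), and Rhbdf2 (39.4 ± 6.34 against 26.4 ± 3.07 CPM), with an adjusted p of 0.785. edgeR called 0 of 14082 genes, with 639 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0 and 0. Without uninjured library 1, in which Apoe lay at 13.21 on the log2 scale against 9.53 to 10.13 in the others, 32 genes were called. In that setting of injury only against uninjured, day 30, 11 disease-associated genes rose (median 0.74, adjusted p = 0.00965 with an estimated correlation). This list test was chosen after the data were seen. Apoe belongs to the list and marked the library left out, so the rise is partly a product of that choice.

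At day 60, 5 genes of the disease-associated program rose after injury, and all 5 are named here. Apoe rose from 927 ± 236 to 11220 ± 4580 CPM (12.1-fold, SE 0.31 on the log2 scale, adjusted p = 8.6e-06 by edgeR, n = 3 and 3). Gpnmb rose from 1.10 ± 1.11 to 32.1 ± 14.9 CPM, Spp1 from 9.77 ± 5.49 to 225 ± 150 CPM, Lgals3 from 12.4 ± 1.26 to 53.6 ± 16.9 CPM and the receptor tyrosine kinase Axl from 59.0 ± 5.31 to 211 ± 81.6 CPM, in 3 of 3 injured libraries each. Adjusted over the list alone, 14 of 25 disease-associated genes rose, and the list was called with either correlation (camera adjusted p = 2.89e-44, adjusted p = 0.0445 with an estimated correlation), as was lipid efflux and storage (1 of 9 genes adjusted over the list alone, adjusted p = 0.0467 with an estimated correlation). P2ry12, at 3445 ± 39.5 against 3962 ± 298 CPM, was not called. The mitochondrial genome list was lower in 8 of 8 cases (0 fell adjusted over the list alone, camera adjusted p = 0.000672, adjusted p = 0.409 with an estimated correlation), with means of 6.30 to 7.36 log2 CPM after injury and 7.25 to 7.87 without. Of 12033 genes, 418 had an unadjusted p under 0.05. DESeq2 called 19 and limma voom 1, and leaving out injury only 4 or uninjured 3, 4 or 5 left 2, 3, 2 and 2 genes. A fit with the library number as a block called 16. On counts thinned to the shallowest library of the day, chosen after the data were seen, 3 genes were called.

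The injury effect differed between the 5 days for 2357 of 17777 genes in 1 test over all libraries (5003 at an unadjusted p under 0.05). Por, the reductase that serves cytochrome P450 enzymes, had a log2 fold change of 1.96 at day 1 and between −0.14 and 0.32 at later days (adjusted p = 2.58e-10 by edgeR). C5ar1, the receptor of complement C5a, was at 2.49 on day 1 and −0.21 on day 7, and Ramp1, a receptor activity modifying protein, at −3.16 and 0.54. Without day 1 the count was 169.

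Clodronate, given to deplete monocytes, was compared with vehicle liposomes to show what differs between these treatments in injured animals. At day 1, genes of mitosis were higher with clodronate. Cdc20 (ENSMUSG00000006398, chromosome 4, 118432901 to 118437352), an activator of the anaphase-promoting complex, rose from 5.01 ± 2.27 to 22.6 ± 9.55 CPM (log2 fold change 2.24, SE 0.34, adjusted p = 0.0138 by edgeR, higher in 6 of 6 clodronate libraries, n = 6 clodronate and 4 vehicle). The cyclin Ccnb2 rose from 2.03 ± 1.07 to 14.7 ± 8.92 CPM and Prc1, a spindle midzone protein, from 3.79 ± 2.71 to 22.3 ± 14.9 CPM. Of 30 cell cycle genes 9 rose (22 adjusted over the list alone, median 2.05, camera adjusted p = 1.05e-30, adjusted p = 0.0748 with an estimated correlation). Clodronate library 2 of the later year had a mean log2 CPM of 3.44 over the list, below both vehicle libraries of that year, the higher at 4.19, and the other later-year clodronate libraries had 5.87 and 5.63. Within library years, Cdc20 had a log2 fold change of 2.67 (SE 0.43, adjusted p = 0.0371 by edgeR) in the earlier and 1.86 (SE 0.49, adjusted p = 0.999) in the later year, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, of 3.58 and 2.53.

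Few genes fell with clodronate at day 1. Ch25h stood at 9.77 ± 5.28 against 24.7 ± 6.81 CPM and the chemokine Ccl12 at 817 ± 196 against 1277 ± 335 CPM, while Klhdc8b and Sarm1, an NAD-cleaving enzyme, fell by 0.89 and 1.47. The log2 fold change of Ch25h was −0.99 in the earlier and −2.00 in the later year, and that of Ccl12 was −0.48 and −0.87. Ccr2, the marker of the monocytes the treatment targets, was at 2.81 ± 1.04 against 7.11 ± 4.10 CPM (adjusted p = 0.0665 by edgeR, lower in 6 of 6 libraries). Within the earlier and the later year its log2 fold change was −1.42 and −1.21. The monocyte list as a set was not called (camera adjusted p = 0.875), and 5 of 5 erythroid genes rose adjusted over the list alone (0 over all genes, camera adjusted p = 2.55e-10, adjusted p = 0.0748 with an estimated correlation). In all, 22 genes rose and 5 fell, with 1212 at an unadjusted p under 0.05. DESeq2 called 112, limma voom 14, a fit of these groups alone 0 and a fit with the library number as a block 127. Within the earlier or the later year alone 3 and 3 genes were called. The count moved to 3, 2 and 8 without clodronate 3, clodronate 4 or vehicle 1 of the earlier year. It moved to 0, 70, 6 and 2 without clodronate 1, clodronate 2, vehicle 1 or vehicle 4 of the later year. Without clodronate 3 of that year 14 genes rose and 5 fell.

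At day 7, disease-associated genes were lower and vascular genes higher with clodronate than with vehicle. Spp1 stood at 923 ± 410 CPM with clodronate and 4570 ± 1400 CPM with vehicle (log2 fold change −2.31, SE 0.30, adjusted p = 0.00362 by edgeR, lower in 5 of 5 clodronate libraries, n = 5 and 4). Gpnmb fell by 1.58 (SE 0.35), from 386 ± 135 to 129 ± 62.0 CPM, the growth factor Igf1 by 1.54, from 80.1 ± 47.6 to 26.2 ± 8.39 CPM, and Cd5l, a secreted scavenger protein of macrophages, by 2.35, from 93.1 ± 49.1 to 18.1 ± 4.50 CPM. Apoe, at 11520 ± 2500 against 20810 ± 6260 CPM, did not pass (adjusted p = 0.0597 by edgeR, lower in 5 of 5 libraries). Injury-only libraries of that day held 727.2 to 1150 CPM of Spp1 and 122.9 to 250.3 CPM of Gpnmb, nearer to the clodronate than to the vehicle means. Their Apoe, at 17860 to 24600 CPM, was nearer to vehicle. Clodronate and injury only were not compared by a test. Of 25 disease-associated genes 3 fell (12 adjusted over the list alone, median −0.44, camera adjusted p = 8.92e-14, adjusted p = 0.0671 with an estimated correlation). The lipid droplet gene Plin2 fell by 0.78 (SE 0.15).

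The vascular genes that rose at day 7 included Cldn5 (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262), from 100.1 ± 47.6 to 299.8 ± 116 CPM, Pecam1, from 47.1 ± 20.5 to 116 ± 17.1 CPM, and Kdr, a receptor of vascular endothelial growth factor, from 54.5 ± 29.9 to 139 ± 28.3 CPM. Angpt2, or angiopoietin-2, and Apln, or apelin, rose by 2.49 (SE 0.49) and 2.08 (SE 0.39). All 13 endothelial and mural genes were higher and 4 rose (11 adjusted over the list alone, median 1.21, camera adjusted p = 2.37e-18, adjusted p = 0.0518 with an estimated correlation). Border macrophage genes were lower in 11 of 12 cases and 1, the folate receptor Folr2, fell to 2.42 ± 1.13 from 10.4 ± 6.44 CPM (8 fell adjusted over the list alone, camera adjusted p = 4.49e-09, adjusted p = 0.143 with an estimated correlation). The glucose transporter Slc2a1 rose from 226 ± 67.1 to 537 ± 132 CPM. Ccr2 was at 8.27 ± 9.66 against 14.5 ± 9.74 CPM (adjusted p = 0.558 by edgeR, lower in 4 of 5 clodronate libraries) and the monocyte list was not called (camera adjusted p = 0.683). In all, 65 genes rose and 17 fell, with 1877 at an unadjusted p under 0.05. DESeq2 called 414, limma voom 210, a fit of these groups alone 0 and a block on the library number 1. Leaving out clodronate 2 or 5 gave 25 and 36 genes, and leaving out vehicle 2, 4 or 5 gave 355, 43 and 12. Lars2 was among the genes that fell (adjusted p = 0.0304 by edgeR) and was not called without vehicle 4 (adjusted p = 0.705 by edgeR). Without vehicle 3, 41 rose and 43 fell, without clodronate 3, 103 and 9, and without clodronate 4, 68 and 7.

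**Figure D3:**
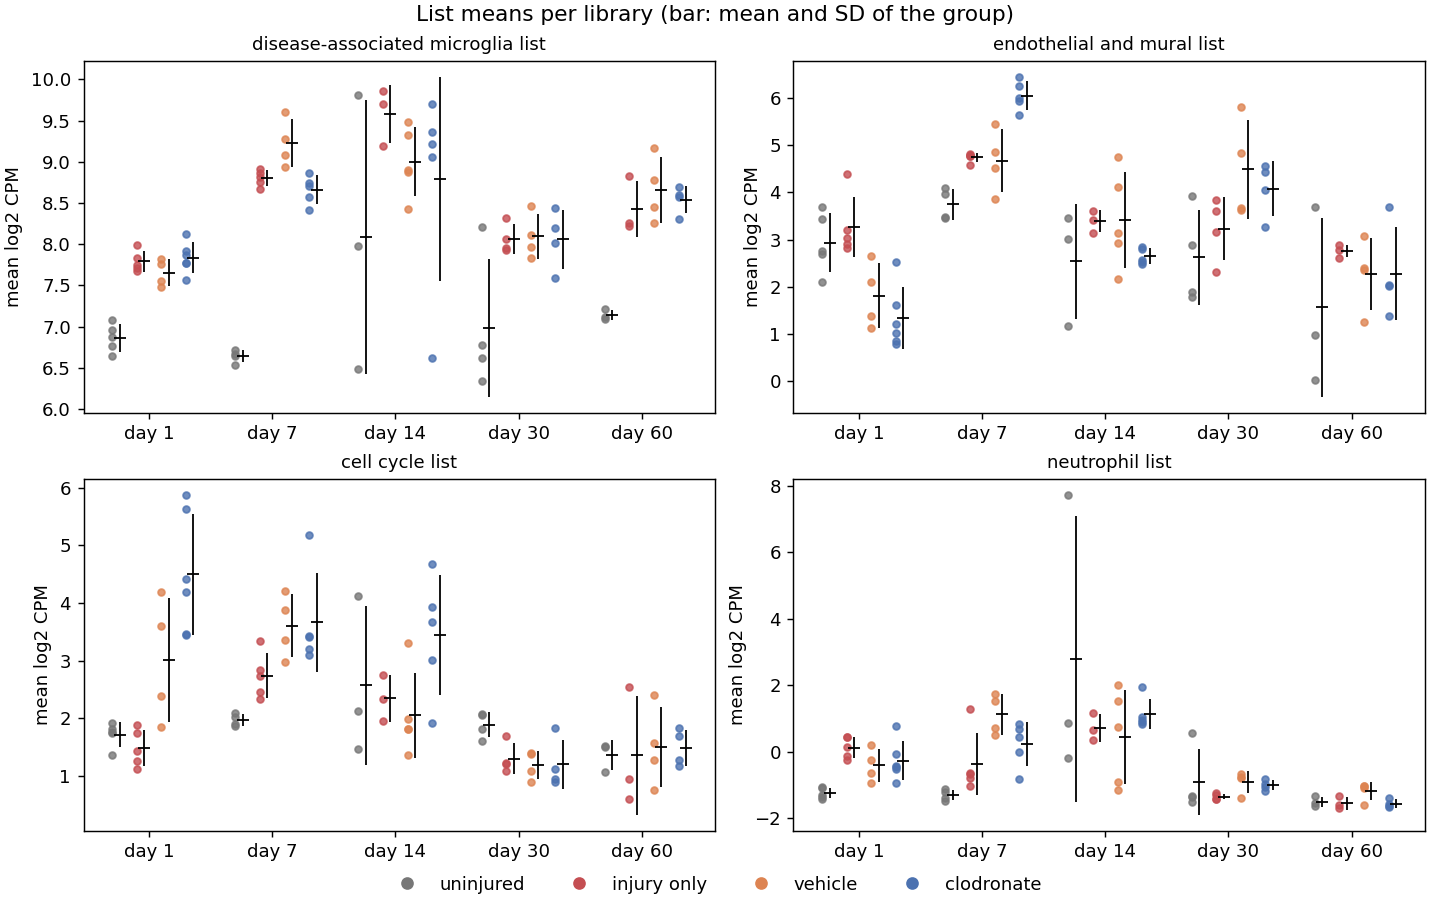
Mean log2 CPM over the disease-associated microglia, endothelial and mural, cell cycle and neutrophil lists in each library (vertical axis) by day and treatment; points are libraries and bars the group mean and SD. At day 7 all 13 endothelial and mural genes were higher with clodronate than with vehicle, with a median log2 fold change of 1.21.

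The genes that injury raised at day 7 were followed in the clodronate comparison, which shares no library with the injury comparison. Of these 877 genes, 570 were higher and 307 lower with clodronate than with vehicle (median log2 fold change 0.34, camera adjusted p = 1.5e-11, adjusted p = 0.207 with an estimated correlation, fry adjusted p = 0.0592). Lists that injury raised at day 7 went both ways with clodronate, with disease-associated and interferon response genes lower and endothelial and mural genes higher. How far genes of other cells account for the higher genes was not tested. Across genes, which are not independent replicates, the injury and clodronate fold changes had a Pearson r of 0.12, 0.28, −0.12, 0.00693 and 0.0331 at days 1, 7, 14, 30 and 60. Among genes with a mean log2 CPM of 3 or more it was 0.219, 0.16, −0.113, 0.078 and 0.0428. The genes that injury raised or lowered at day 1, and those it lowered at day 7, were not called as sets (camera adjusted p = 0.166 each).

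At day 14, Il1b was at 1364 ± 791 CPM with clodronate and 511 ± 687 CPM with vehicle, and 1 library in each group stood apart (n = 5 and 5). Clodronate library 1 held 1414 CPM of Apoe and 4234 CPM of P2ry12, whereas clodronate libraries 2 to 5 held 60640 to 66160 and 906.2 to 1123 CPM. Vehicle library 1 held 1033 CPM of P2ry12 and 1835 CPM of Il1b, against 2648 to 3419 and 163.2 to 259.6 CPM in vehicle libraries 2 to 5. Cell cycle genes were higher in 29 of 30 cases (0 called adjusted over the list alone, median 1.49, camera adjusted p = 1.26e-20, adjusted p = 0.395 with an estimated correlation), and all 24 cytokine and NF-kB genes were higher (median 0.50, camera adjusted p = 1.89e-05, adjusted p = 0.412 with an estimated correlation). The smallest p-values were those of Stk39, Slc16a8 and Lrrn2, with an adjusted p of 0.794. edgeR called 0 genes, with 785 at an unadjusted p under 0.05. DESeq2 called 17 and limma voom with quality weights 2954. Without clodronate library 1 and vehicle library 1, left out after the data were seen, 208 genes were higher and 101 lower. In that setting of clodronate against vehicle, day 14, 4 cell cycle genes (median 2.12) and 6 cytokine genes (median 0.95) rose. Monocyte genes rose with them in 2 of 14 cases (median 1.55), with list means of 2.74 to 3.32 log2 CPM in clodronate libraries 2 to 5 and 0.93 to 1.35 in vehicle libraries 2 to 5. The libraries left out stood apart in this same list mean (0.2041 in clodronate 1 and 3.123 in vehicle 1), and vehicle 1 also in Il1b. The gap between the remaining libraries is therefore partly a product of that choice.

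At day 30, MHC class I genes were higher with clodronate than with vehicle in 14 of 14 cases, and 12 rose adjusted over the list alone (0 over all genes, median 0.54, camera adjusted p = 6.58e-11, adjusted p = 0.352 with an estimated correlation). Clodronate library 4 had a mean log2 CPM of 8.52 over this list, against 7.43 to 7.77 in clodronate libraries 1 to 3 and 7.35 to 7.46 in vehicle libraries, and held 1497 CPM of H2-Ab1 against 165 to 211 in clodronate libraries 1 to 3. Means of the B cell list were 1.02 to 2.37 log2 CPM with clodronate and 0.27 to 0.73 with vehicle (1 of 4 genes rose adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.514 with an estimated correlation). Those of the T and NK cell list were −1.71 to −1.26 and −2.24 to −1.88. Clodronate library 4 also held 4406 CPM of Cd74 and 59.4 CPM of the immunoglobulin gene Igkc. Border macrophage genes were lower in 11 of 12 cases (2 fell adjusted over the list alone, camera adjusted p = 0.000914, adjusted p = 0.352 with an estimated correlation). Apoe was at 8581 ± 3680 against 9565 ± 4290 CPM (adjusted p = 0.957 by edgeR, lower in 3 of 4 clodronate libraries, n = 4 and 4). Atp8b1, Kat6a and Gm13479 had the smallest p-values, each with an adjusted p of 0.209; the acetyltransferase gene Kat6a stood at 23.9 ± 1.90 against 41.9 ± 10.7 CPM. edgeR called 0 genes, with 1199 at an unadjusted p under 0.05. DESeq2 called 33, limma voom 135 and, without vehicle library 1, edgeR 140.

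At day 60, the mitochondrial genome transcripts were lower with clodronate in 8 of 8 cases and 7 fell adjusted over the list alone (0 over all genes, median −0.97, camera adjusted p = 9.98e-16, adjusted p = 0.262 with an estimated correlation). The list's mean log2 CPM was 7.28 to 7.49 in vehicle libraries, which held 1109856 to 5271285 counts, and 7.12 in clodronate library 2, with 2150009 counts. It was 5.97 to 6.42 in the other clodronate libraries, with 6558102 to 9694385 counts, and 7.25 to 7.87 in uninjured libraries, with 2930843 to 3739798 counts. Injury-only libraries had 6.30 to 7.36, with 8431455 to 12306417 counts. The heat shock gene Hsph1 was at 446 ± 123 against 168 ± 56.5 CPM and clusterin (Clu) at 83.3 ± 37.9 against 24.5 ± 4.52 CPM, each with an adjusted p of 0.474 (n = 4 and 4), and Apoe at 13460 ± 2330 against 10000 ± 3600 CPM. edgeR called 0 genes, with 789 at an unadjusted p under 0.05. DESeq2 called 17, limma voom 0 and a fit with the library number as a block 10. Without clodronate library 1, 1 gene was called.

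The clodronate effect differed between days for 48 genes (2173 at an unadjusted p under 0.05). Lars2, the gene of mitochondrial leucyl-tRNA synthetase, had a log2 fold change of −5.70 at day 7 and between −0.22 and 0.48 on other days (adjusted p = 7.97e-06 by edgeR), and the mitochondrial ribosomal RNA mt-Rnr2 one of −3.16 at day 7. Both values came from vehicle library 4 of day 7, with 225700 CPM of Lars2 and 27900 CPM of mt-Rnr2. The other vehicle libraries held 830.3 to 985.4 and 529.8 to 1372 CPM, and the clodronate libraries 929.4 to 1095 and 553.9 to 1045 CPM. Without it the day 7 log2 fold changes were 0.15 (SE 0.11, adjusted p = 0.705 by edgeR) and −0.12 (SE 0.30, adjusted p = 0.943). Ptgds, prostaglandin D2 synthase, and Car2, a carbonic anhydrase, were at 1.64 and 1.44 on day 7 and −2.48 and −2.16 on day 14. Ttr and Clic6, genes of the choroid plexus, were called beside them, at 1.56 and −1.99 and at 1.38 and −1.98 on these days. No list of choroid plexus genes was tested. Whether these calls hold without day 7 vehicle library 4 is not given here. Without day 7 vehicle library 4 the count was 7, and without day 1 or day 60 it was 14 and 20.

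Vehicle was compared with injury only to show what the liposomes themselves change, and shares the vehicle libraries with the clodronate comparison and the injury-only libraries with the injury comparison. At day 1, inflammatory genes were lower with vehicle liposomes. Within the earlier library year, which holds both groups, Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) was at 242 ± 77.0 CPM with vehicle and 849.7 ± 306 CPM without (log2 fold change −1.81, SE 0.31, n = 2 and 5), and over all libraries it fell by 1.57 (SE 0.29, adjusted p = 0.0088 by edgeR, lower in 3 of 4 vehicle libraries). Csf1, a growth factor of microglia, was at 184 ± 31.6 against 574 ± 26.3 CPM in that year (pooled log2 fold change −1.67), the costimulatory ligand Tnfsf9 at 47.4 ± 4.81 against 269 ± 80.3 CPM (−2.24), and Pfkfb3, a regulator of glycolysis, at 277 ± 45.2 against 720.5 ± 45.0 CPM (−1.36). Of 24 cytokine and NF-kB genes 4 fell (11 adjusted over the list alone, median −0.69, camera adjusted p = 1.08e-07, adjusted p = 0.33 with an estimated correlation). Endothelial genes Flt1 and Ly6c1 fell by 2.45 and 2.77 (2 of 13 list genes fell, 6 adjusted over the list alone, camera adjusted p = 7.48e-09, adjusted p = 0.33 with an estimated correlation). Within the earlier year they were at −2.04 and −2.41 and not called. Injury only 1 stood apart in this list, with a mean of 4.383 log2 CPM against 2.82 to 3.21 in the other injury-only libraries. Altogether 30 genes rose, led by Zcchc2 and Mid1, a microtubule-associated ubiquitin ligase, and 97 fell, with 2057 at an unadjusted p under 0.05. DESeq2 called 409 and limma voom 222, a fit of these groups alone 14, and leaving out injury only 1, injury only 2 or vehicle 2 of the earlier year gave 46, 67 and 26. Without vehicle 1 of the earlier year 14 genes rose and 92 fell.

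At day 7, cytokine genes were higher with vehicle than with injury only. Il1b rose with vehicle from 125 ± 37.6 to 449.6 ± 218 CPM (log2 fold change 1.86, SE 0.38, adjusted p = 0.0305 by edgeR, higher in 4 of 4 vehicle libraries, n = 4 vehicle and 5 injury only), Ptgs2, or cyclooxygenase-2, from 24.9 ± 8.99 to 95.7 ± 37.3 CPM and Tnfsf9 from 11.2 ± 3.96 to 53.6 ± 18.2 CPM. Whether this effect differs between days was not tested. Spp1 rose from 974 ± 205 to 4570 ± 1400 CPM and Cd5l from 19.7 ± 12.1 to 93.1 ± 49.1 CPM. Both fell from these same vehicle libraries to the clodronate libraries, so the 2 comparisons share chance values. Of 24 cytokine and NF-kB genes 2 rose (16 adjusted over the list alone, median 0.72, camera adjusted p = 1.85e-16, adjusted p = 0.0603 with an estimated correlation). Neutrophil genes were higher with vehicle in 8 of 9 cases (2 rose adjusted over the list alone, median 2.18, camera adjusted p = 1.25e-05, adjusted p = 0.0603 with an estimated correlation), with S100a8 at 0.90 to 10.8 CPM against 0 to 3.23 CPM. The astrocyte connexins Gja1 and Gjb6 fell by 1.94 and 3.16 (1 of 8 astrocyte genes fell, 1 adjusted over the list alone, camera adjusted p = 0.00141, adjusted p = 0.0695 with an estimated correlation). Meg3, a long non-coding RNA of neurons, fell by 2.29 (1 of 12 neuron genes fell, 4 adjusted over the list alone, camera adjusted p = 2.03e-07, adjusted p = 0.126 with an estimated correlation). In all, 28 genes rose and 20 fell, with 1730 at an unadjusted p under 0.05. DESeq2 called 250, limma voom 123, a fit of these groups alone 17 and a block on the library number 29. Leaving out injury only 1, 2 or 3 gave 30, 21 and 26 genes, and vehicle 2 or 5 gave 91 and 15. Without injury only 4, 17 genes rose and 20 fell, and without vehicle 3, 55 and 12.

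At day 30, endothelial and mural genes were higher with vehicle than with injury only in 13 of 13 cases and 6 rose adjusted over the list alone (0 over all genes, median 1.68, camera adjusted p = 1.27e-08, adjusted p = 0.577 with an estimated correlation). Vehicle library 1, the library with 87.46% of reads uniquely aligned, had a mean log2 CPM of 5.82 over this list and 229 CPM of Cldn5. Vehicle libraries 2 to 4 had means of 3.63 to 4.83, and injury-only libraries of 2.32 to 3.85. Neuron genes were lower in 12 of 13 cases (3 fell adjusted over the list alone, camera adjusted p = 2.37e-07, adjusted p = 0.577 with an estimated correlation). Chsy1, a chondroitin synthase, was at 22.6 ± 4.17 against 48.0 ± 11.5 CPM (adjusted p = 0.104 by edgeR, lower in 4 of 4 vehicle libraries, n = 4 and 4). edgeR called 0 genes, with 1212 at an unadjusted p under 0.05. DESeq2 called 35, limma voom 8 and a fit with the library number as a block, which paired these groups, 2. Leaving out injury only 1 or vehicle 1 gave 1 and 8 genes. At day 60, Hsph1 (ENSMUSG00000029657, chromosome 5, 149614287 to 149636376), a heat shock protein of the HSP110 family, fell from 696 ± 247 to 168 ± 56.5 CPM (log2 fold change −2.06, SE 0.30, adjusted p = 0.0172 by edgeR, lower in 4 of 4 vehicle libraries, n = 4 vehicle and 3 injury only). MHC class II genes were higher in 8 of 9 cases, 4 of them called adjusted over the list alone (camera adjusted p = 3.65e-07, adjusted p = 0.118 with an estimated correlation). Border macrophage genes were higher in 10 of 10 cases (0 called adjusted over the list alone, camera adjusted p = 0.000613, adjusted p = 0.114 with an estimated correlation), and Ccr2 was at 18.87 ± 7.39 against 6.75 ± 3.36 CPM (adjusted p = 0.758 by edgeR, higher in 4 of 4 vehicle libraries). Erythroid genes were lower in 4 of 4 cases, 4 of them called adjusted over the list alone (camera adjusted p = 6.28e-09, adjusted p = 0.114 with an estimated correlation). Hsph1 was the 1 gene called, with 695 at an unadjusted p under 0.05. DESeq2 called 29 and limma voom 8, a fit of these groups alone 0 and a block on the library number 0. The count was 9, 0 and 7 without injury only 2, 3 or 4, and 0, 4 and 0 without vehicle 1, 2 or 4.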

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

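The tests of the libraries of days 14 and 30 that stand apart, of endothelial cells and of other cell types carried over at day 7 were chosen after the result was seen. A library was singled out where its gap to the nearest other library of its group, divided by the group's range, passed Dixon's 95% value. Chance does so in about 1 of 20 groups, and it happened in 30 of 182 groups and measures examined. These were 13 measures in the 14 groups of 4 to 10 libraries. Smaller groups, among them uninjured and injury only of day 14, were not examined in this way.

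At day 14, clodronate library 1 stood apart in P2ry12 (12.05 against 9.824 to 10.13 log2 CPM in the others, ratio 0.861), Apoe (10.47 against 15.89 to 16.01, ratio 0.977), total count (0.764) and the monocyte list mean (0.2041 against 2.744 to 3.319, ratio 0.815). Vehicle library 1 of that day stood apart in P2ry12 (10.01 against 11.37 to 11.74, ratio 0.786), Il1b (10.84 against 7.355 to 8.023, ratio 0.808) and the monocyte list mean (3.123 against 0.9346 to 1.352, ratio 0.809). Clodronate library 2 did so in the neutrophil list mean (0.792). At day 30, Apoe stood apart in uninjured library 1 (13.21 against 9.529 to 10.13, ratio 0.836), Il1b in injury only 3 (0.863) and vehicle 3 (0.874), H2-Ab1 in clodronate 4 (10.55 against 7.372 to 7.721, ratio 0.89). Other ratios of that day were those of the total count in vehicle 3 (0.912), the percent uniquely aligned in vehicle 1 (87.46% against 89.29% to 89.51%, ratio 0.893) and the neutrophil list mean in uninjured 2 (0.904).

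At day 7, vehicle library 4 stood apart in total count (1134000 against 13080000 to 13720000, ratio 0.95) and percent uniquely aligned (54.62% against 90.23% to 90.41%, ratio 0.995). P2ry12 stood apart in uninjured library 1 (12.43 against 12.15 to 12.19, ratio 0.883) and clodronate library 1 (10.47 against 11.12 to 11.34, ratio 0.744), and the neutrophil and endothelial list means in injury only 1 (0.84 and 0.817). At day 1 it was Ifit3 in uninjured 3 (0.856), the percent uniquely aligned in uninjured 5 (0.72) and the endothelial list mean in injury only 1 (4.383 against 2.82 to 3.21, ratio 0.75). At day 60 it was the percent uniquely aligned in clodronate 2 (77.66% against 86.68% to 87.2%, ratio 0.945) and the neutrophil list mean in vehicle 4 (0.86). Ly6c2 was detected in 1 library and at 0 counts in the others of uninjured groups of days 7 and 30 and of clodronate and vehicle groups of day 60, which makes the ratio 1.

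By a test of the difference itself, the injury effect differed between days for 2357 genes and the clodronate effect for 48. The clodronate effect at day 1 differed between library years for 2 of 14516 genes, with 668 at an unadjusted p under 0.05.

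Libraries of days 14 and 30 stood apart from their groups. Blood cells in day 14 uninjured library 3, which held 825 CPM of Ccr2 and 465 CPM of Ly6c2, are a candidate source of its difference, with 92.9% of tested monocyte and neutrophil genes higher there than in both other uninjured libraries. A wrong label may apply to uninjured library 1 of day 14, whose disease-associated mean of 9.805 log2 CPM lay within the 9.187 to 9.861 of injury-only libraries (6.489 and 7.973 in uninjured 2 and 3), and to vehicle library 1, whose homeostatic mean of 9.827 lay within the 9.727 to 9.921 of clodronate 2 to 5 (10.45 to 10.61 in vehicle 2 to 5). Uninjured library 1 of day 30 had a disease-associated mean of 8.21, within the 7.926 to 8.314 of injury-only libraries of that day (6.339 to 6.777 in the other uninjured libraries), so a wrong label stays open there too. Clodronate library 1 of day 14, at 6.62, lay beside uninjured library 2, at 6.489, and a wrong label of it alone was not tested. An exchange of clodronate 1 and vehicle 1 is not settled. The disease-associated mean of clodronate 1 lay far under the 8.424 to 9.327 of vehicle 2 to 5, which goes against it. The labelling with these libraries exchanged called 874 genes, against 0 for the labels as given. Both libraries were singled out because they stood apart from their groups. Their exchange makes the groups more alike whatever the cause, so this count cannot decide the question. Of the 3 uninjured libraries that stood apart, 1 had the lowest total of its group, uninjured 3 of day 14. Low depth is argued against for the others. Clodronate 1 also had the lowest total of its group (9534000 against 14750000 to 16360000), so for it low depth stays open. Uninjured 3 held more raw counts of Ccr2 (7322 against 203 and 206 in uninjured 1 and 2) and of S100a8 (10660 against 20 and 17). Fewer reads do not raise a raw count, so low depth alone is argued against for its higher blood cell genes. A difference between animals or injuries stays open and was not tested.

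Endothelial and mural genes were higher with clodronate at day 7. Of the tested list genes 13 of 13 were higher, with Cldn5 at 299.8 and Kdr at 139 CPM. Endothelial cells carried over into the clodronate libraries cannot be told apart from a change of vascular cells, since this count restates the pattern and the gates of the sort are not given in the sources used here. Vehicle library 4 is argued against, because the median log2 fold change was 1.25 without it and 1.21 with it. A like carry-over of neurons, astrocytes and oligodendrocytes is argued against for these lists as sets, because their highest median was 0.0774. Cells outside these lists are not covered. The choroid plexus genes Ttr and Clic6 were at log2 fold changes of 1.56 and 1.38 with clodronate at day 7. A change of vascular cells or of their yield under clodronate stays open and was not tested.

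Cell cycle genes were higher with clodronate at day 1. Library year as the whole cause is argued against by a median log2 fold change of 1.61 in the lower of the years, and a single library by a lowest median of 1.88 when each was left out. Dividing blood cells cannot be told apart from dividing microglia. The highest median of the monocyte and neutrophil lists was 0.13, but their members went both ways, and T and NK cell genes were too few to test. The erythroid list, which was higher with clodronate in this comparison, was not part of that test. A biological effect of clodronate stays open as a hypothesis.

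Other splits of the same libraries bear on chance. Chance is argued against for injury at day 1 (1 of 100 splits as large, 4906 genes, highest other 143) and day 7 (1 of 100, 1097, 259). The share was as low for clodronate at day 7 (1 of 100, 82, 7) and vehicle at day 7 (1 of 100, 48, 1). Both comparisons rest on the same vehicle libraries. Without vehicle 5 their counts were 12 and 15, so chance is not excluded for them. The shares were not adjusted for the number of comparisons. For vehicle at day 1 (1 of 21; 127, 0) the share was under 0.05 but the smallest possible, and only earlier-year libraries were relabelled. For the injury effect between days (1 of 24; 2357, 266), relabelling within each day removes the injury effect itself. Those splits bear on an injury effect at any day, and not on a difference between days. Chance cannot be excluded for clodronate at day 1 (6 of 100; 27, 555), for vehicle at day 60 (5 of 35; 1, 3) and for the clodronate effect between days (2 of 24; 48, 57). Where the real count was 0, every split is as large by construction, so the splits say nothing about chance. This holds for clodronate at day 14 (100 of 100, highest other 874), day 30 (35 of 35, 1114) and day 60 (35 of 35, 1), for injury at day 30 (35 of 35, 0) and for vehicle at day 30 (35 of 35, 3). At days 14 and 60 the injury comparison had 10 splits, too few for a share under 0.05 (10 of 10 with a real count of 0 and a highest other of 2, and 1 of 10 with 5 and 0). The splits with 555, 874 and 1114 genes point to a structure among the libraries. At day 14 that split set clodronate 1 and vehicle 2 to 5 against the rest, which is the labelling with clodronate 1 and vehicle 1 exchanged. At day 30 it set vehicle 1 with clodronate 1, 2 and 4 against the rest.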

How the results depend on the processing

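The tests that left out doubted libraries, and those on thinned counts, were chosen after the data were seen. Among called genes named within a day, direction was kept in every alternative run. Lars2, named from the test between days, was at −5.84 at day 7 and at 0.15 without vehicle library 4 (adjusted p = 0.705). With DESeq2 the call was kept by 304 and lost by 1, with DESeq2 size factors by 303 and 2, with limma voom by 283 and 22, with no low-count filter by 302 and 3, and in a fit of the compared groups alone by 217 and 81. In the earlier library year of day 1 alone 142 kept the call and 22 lost it, in the later year alone 16 lost it, and on thinned counts 4 kept and 2 lost it. Over all libraries left out in turn, 2377 calls were kept and 485 lost. The cause was not tested. Libraries held as few as 1109856 counts at day 60 and 1134078 at day 7, which limits what can be detected there.

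Counts of called genes moved by more than 1.5 times as follows. With DESeq2 they were 97 and 19 for injury at days 14 and 60 (0 and 5 before), 112, 414, 17, 33 and 17 for clodronate at days 1, 7, 14, 30 and 60 (27, 82, 0, 0 and 0), and 409, 250, 35 and 29 for vehicle at days 1, 7, 30 and 60 (127, 48, 0 and 1). With limma voom they were 1958 and 1 for injury at days 7 and 60, 14, 210, 2954 and 135 for clodronate at days 1, 7, 14 and 30, 222, 123, 8 and 8 for vehicle, and 3567 and 1594 for the injury and clodronate effects between days. With no low-count filter they were 37 for injury at day 60, 382, 339, 26 and 77 for clodronate at days 1, 7, 30 and 60, 840, 222, 17 and 85 for vehicle, and 135 for clodronate between days. A fit of the compared groups alone called 1 and 1 for injury at days 30 and 60, 0 and 0 for clodronate at days 1 and 7, and 14, 17 and 0 for vehicle at days 1, 7 and 60. In the earlier or later library year alone clodronate at day 1 gave 3 and 3. Thinned counts gave 3 for injury and 5 for vehicle at day 60. Between days, injury gave 169 without day 1, and clodronate 20 without day 60, 14 without day 1 and 7 without day 7 vehicle library 4. Without uninjured libraries 1 and 3 injury at day 14 gave 2529, a count that rests on the 1 uninjured library left and on the spread within other groups. Without clodronate 1 and vehicle 1 clodronate at day 14 gave 309. The cause was not tested.

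With each library left out in turn, injury gave 4360 to 4719, 592 to 1068, 0 to 1835, 0 to 32 and 2 to 6 genes at days 1, 7, 14, 30 and 60. Clodronate gave 0 to 70, 12 to 355, 0 to 0, 0 to 140 and 0 to 1, and vehicle 26 to 177, 15 to 91, 0 to 8 and 0 to 9 at days 1, 7, 30 and 60. The libraries that moved a count by over 1.5 times are named beside each comparison.

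A block on the library number gave 16 genes for injury at day 60, 127, 1 and 10 for clodronate at days 1, 7 and 60, and 29, 2 and 0 for vehicle at days 7, 30 and 60. By the rule of every pair above 0.1, the numbers pair libraries for vehicle at day 30 alone. Same-numbered pairs of injury at day 30 correlated at 0.0744 to 0.215. Those of clodronate at day 30 averaged 0.137, against −0.047 for other numbers, so a weaker pairing is not excluded there. Correlations were −0.693 to −0.057 for clodronate at day 14, where library 1 of each group stood apart, with a lowest of −0.155 at day 7. Among comparisons with 3 or more pairs, none had every library correlate best with its own number, and the highest was 5 of 8, for vehicle at day 30. The block kept 245 named gene calls and 53 were lost. Among lists it kept 98 calls, 12 were lost, and 2 changed sign: mitochondrial genome for injury at day 60 (adjusted p = 0.601) and oxidative phosphorylation for clodronate at day 1 (0.131).

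Of 112 state and quality list calls, 7 held with an estimated correlation and 36 with fry, which called 40 of the state and quality lists. Of 49 cell type list calls 1 held with an estimated correlation. Of the injury gene sets under clodronate 0 were called with an estimated correlation and 0 with fry, against 1 by camera. Without doubted libraries 104 list calls were kept, 3 lost and 5 reversed: homeostatic (adjusted p = 0.778), oxidative phosphorylation (0.83) and ribosomal proteins (0.121) for injury at day 14, and ribosomal proteins for clodronate (0.00145) and vehicle (0.151) at day 7. The day 14 reversals rest on 1 uninjured library. The cause was not tested.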

Other observations

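All values here come from tests planned before the data were examined, except those said to leave out a library. Dividing-cell genes were higher with vehicle liposomes than with injury only at days 1 and 7. At day 7, 30 of 30 cell cycle genes were higher with vehicle, with a median log2 fold change of 1.01, and at day 1 28 of 30 with a median of 0.98. Adjusted over the list alone, 11 of them rose on each day and 0 over all genes (camera adjusted p = 1.92e-11 and 4.77e-10 at days 7 and 1, adjusted p = 0.254 and 0.33 with an estimated correlation).

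Interferon response genes, which injury raised at day 7, were lower with clodronate than with vehicle in 24 of 26 cases, with a median of −0.34 (0 fell over all genes and 4 adjusted over the list alone, camera adjusted p = 5.14e-05, adjusted p = 0.519 with an estimated correlation). MHC class II genes were lower in 7 of 9 cases, with 4 that fell adjusted over the list alone (camera adjusted p = 0.00137, adjusted p = 0.475 with an estimated correlation). Mitochondrial genome transcripts were lower in 8 of 8 cases with clodronate (median −1.04; 6 fell adjusted over the list alone, camera adjusted p = 0.000319, adjusted p = 0.475 with an estimated correlation). In clodronate against vehicle, day 7, without vehicle replicate 4, the mitochondrial genome list had a median of −0.25 (camera adjusted p = 0.149). That library's list mean was 7.377 log2 CPM, against 4.794 to 6.106 in the other vehicle and 4.877 to 5.298 in the clodronate libraries. Mpeg1, the perforin of macrophages, was at −1.51 on the log2 scale at day 7 and between −0.68 and 0.53 on other days. These values come from the test of the clodronate effect between days, for which chance could not be excluded. Its count of called genes fell without day 7 vehicle library 4, and the value of Mpeg1 without that library is not given here.

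At day 60, border macrophage genes were higher after injury in 8 of 10 cases (3 rose adjusted over the list alone, median 0.93, camera adjusted p = 0.00359, adjusted p = 0.148 with an estimated correlation) and 10 of 10 were higher with vehicle than with injury only (camera adjusted p = 0.000613, adjusted p = 0.114 with an estimated correlation). MHC class II genes rose after injury in 4 of 9 cases adjusted over the list alone (0 over all genes, camera adjusted p = 0.000672, adjusted p = 0.409 with an estimated correlation). Heat shock and immediate early genes were higher with clodronate than with vehicle in 19 of 22 cases at day 60 (4 rose adjusted over the list alone, camera adjusted p = 5.5e-08, adjusted p = 0.633 with an estimated correlation).

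Several genes had a larger log2 fold change with injury at day 1 than at day 7. Glrx, or glutaredoxin, was at 3.62 on day 1 and 0.96 on day 7, the RNA-binding gene Ybx3 at 2.28 and 0.18, the serine hydroxymethyltransferase Shmt2 at 1.83 and 0.04, and spermidine synthase (Srm) at 1.51 and −0.22 (adjusted p from 5.21e-09 to 2.8e-08 by edgeR in the test between days).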
